A study of Mus musculus with 21 samples.

How the data were processed

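CSR-HTGTS-seq was run on genomic DNA of CH12F3 cells, a mouse B lymphoma line that switches from IgM to IgA when stimulated. The assay reads the joins between a fixed DNA end, the bait, and the sequence it was joined to, the prey. The bait lay at the 5′ end of the Sμ switch region. Per the labels, all cells were stimulated with anti-CD40, IL4 and TGF-β for 72 h. The series holds 21 libraries in 5 groups, named after the labels' genotypes. NCdel (n = 6) is the starting line, in which the non-productive IgH allele lacks the segment from Sμ to Sα, so that the productive allele alone is read. Iadel (n = 6) also lacks Iα, the promoter and first exon of germline transcription through Sα. i3CBEc (n = 3) carries 3 inserted CTCF-binding elements (CBEs) in the NCdel line, in what the labels call the convergent orientation. Iadel-i3CBEc (n = 3) carries the 3 CBEs downstream of Cγ2a in Iα-deleted cells. i3CBEc-3CBEdel (n = 3) carries the insertion and lacks the 3′CBEs, the cluster of CTCF sites beyond the 3′ end of the constant genes.

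The deposited files are the authors' junction tables, with 1 line per kept junction, positions in bases of the mm9 build and other read coordinates in bases, and no normalisation. The submitters' processing notes name mm9 and Bowtie2, with no version. The files hold flag columns of the upstream filters, among them mapping quality, repeat sequence and duplicate, and no deposited line carries a flag. They state neither the settings of these filters nor molecular identifiers. The read names hold 8 sequencing runs, of which run 490 holds libraries 1 to 3 of NCdel, libraries 4 to 6 of Iadel and all 3 libraries of Iadel-i3CBEc. No other run holds more than 1 group.

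The file of Iadel library 4 held 4614 junctions, of which 1760 are the reads of Iadel library 5 and 1315 those of library 6. These 3075 reads were removed from library 4, which left 1539. In the libraries of the 3 insertion groups, positions on the μ side of a step in chromosome 12 are shifted by 99 bases against the other libraries. Reads of both kinds were compared by their words of 40 bases. Of 15046 matched words, 8594 lay at the same position and 6401 at a shift of 99 bases. None contradicted a step between positions 114521585 and 114526803, and 51 had another shift. The shift was removed on the μ side of this interval, so that positions there are on the mm9 scale of the libraries without an insertion. The exact insertion site is not given by the labels and lies at an unknown point between 114521585 and 114526803. In the insertion libraries, positions within the interval, and within 99 bases of it on the μ side, were therefore kept as deposited. They may be off by up to 99 bases. After these steps 40530 junctions were used, 1180 to 3513 per library. Repeats of a prey position, strand and bait end made up 0.38% to 1.36% of a library and were kept.

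No mm9 annotation was at hand. Switch regions were therefore placed by the density of the AGCT motif in the prey reads, taken in 1-kb bins with at least 1000 bases read and at least 1 motif per 100 bases, with bins merged within 3 kb. There were 8 such blocks. The last, at 114464000 to 114464999 beyond the constant genes, had 1.14 motifs per 100 bases over 10874 bases read and was not named. The other 7 were named by the order of the 8 constant genes in a gene table of another build, which was used for order alone and for no position. Region borders were set between blocks. The labels write Cγ2a where that table has Ighg2c, and the block there is called Sγ2a. The design had 1 unit for γ2a. It was divided after the positions were seen into the γ2a unit, from the Sγ2a block towards γ2b, and the stretch between Sγ2a and Sε, which holds the place of Cγ2a and of the insertion. Values for both together are also given. The acceptor regions are γ3, γ1, γ2b, γ2a, the stretch, ε and α. The window ran from 20 kb upstream to 250 kb downstream of the bait, and a junction beyond it is called outside IgH. The term means outside this window. The borders of the IgH locus were not placed, so such junctions may include some within the locus upstream of the bait.

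The share of a region is its percent of all junctions of a library. Group values are the mean ± SD over libraries. Intervals for single libraries are 95% Wilson intervals, and a count of 0 is given the limit of 3 junctions over the total. PCR reads without molecular identifiers are not independent molecules, so intervals and limits cover counting error only. Folds are ratios of group means. A fold against a group at 0 uses the limit of 3 junctions over the group's total and is a lower bound.

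Region shares were compared by two-sided exact permutation tests of the difference in group means, with Benjamini-Hochberg adjustment over the 10 regions of a comparison. The smallest p is 0.00216 for 6 against 6 libraries (924 splits), 0.0119 for 3 against 6 (84 splits) and 0.1 for 3 against 3 (20 splits). The last kind cannot pass 0.05. The acceptor total and the share outside IgH were tested on their own. The insertion effect with and without the Iα deletion was compared by permuting the insertion label within each background (7056 relabelings). This has no insertion effect in either background as its null, so after seeing the data it was repeated with a common effect, in percentage points, taken out of the insertion libraries first; the p given is the largest over 101 common effects between the 2 observed ones. Orientation and join structure were tested the same way, in libraries with at least 10 junctions in the region. A prey on the bait's strand is called deletional and the other kind inversional, in every region. Upstream of the bait and outside IgH the terms name the strand alone, since such a join is no deletion towards an acceptor region. The labels do not say whether libraries come from separate cultures, so p-values measure the spread between these samples.

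For positions within regions, junctions in 1-kb bins with at least 10 junctions over all libraries were fitted with limma 3.58.1 in R 4.3.3, as log2 of junctions plus 0.5 per 10000, with a mean per group over all 21 libraries, empirical Bayes with a trend, and an adjusted p threshold of 0.05 over 60 bins. A bin can pass the filter of 10 junctions through 1 group alone, which partly fixes the direction of its call in advance. Simulated counts were drawn around bin means over all groups, with a negative binomial size of 10 and no run effect. The rates hold for that setting and may not carry over where real libraries spread more widely. On these simulated data with 20 of 60 bins changed, the fit recovered 100% of 16-fold changes in every comparison except i3CBEc-3CBEdel against i3CBEc (90%). For 4-fold changes it recovered 90% in Iadel against NCdel and in Iadel-i3CBEc against Iadel. It recovered 70% in i3CBEc-3CBEdel against NCdel, 50% in Iadel-i3CBEc against i3CBEc, 40% in i3CBEc against NCdel and 20% in i3CBEc-3CBEdel against i3CBEc. It called 3 of 40 unchanged bins in Iadel-i3CBEc against Iadel, 1 of 40 in i3CBEc-3CBEdel against i3CBEc and 0 in the others. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

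The comparisons, tests, alternatives and the rule for named items were set before the data were examined. The rule names every constant-region unit, up to 12 bins per comparison with the largest log2 fold among those past the threshold whose libraries do not overlap between groups, and up to 10 bins of 100 kb outside IgH with the most junctions in at least 3 libraries. A preset list of genes reported as off-targets of AID, with Igk and Igl, could not be placed without an mm9 annotation and was not analysed here. The alternatives set in advance were other denominators (acceptor junctions, junctions of the μ unit, or without 10 kb around the bait), repeats counted once, deletional joins only, leaving out each library, the replicate number as a block, libraries 1 to 3 or 4 to 6 of the 6-library groups, 5-kb bins, a pseudocount of 2, other filters and voom weights. Chosen after seeing the data were the tables as deposited (library 4 of Iadel, and the coordinates), run 490 alone, log2 shares, the Sα block alone, and the common insertion effect taken out.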

Results

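The series asks, by its title and design, what chromatin loop extrusion contributes to antibody class switching, and these libraries read where broken Sμ ends were joined in stimulated CH12F3 cells of 5 genotypes. There were 6 libraries of NCdel, 6 of Iadel, 3 of i3CBEc, 3 of Iadel-i3CBEc and 3 of i3CBEc-3CBEdel. The totals were 11564, 14644, 3828, 5152 and 5342 junctions, in that order. A library held 1180 to 3513 junctions.

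The switch blocks, the AGCT-rich stretches that AID targets, lay on chromosome 12 of mm9. They were named by the order of the constant genes, so that their order is no result. The bin at 114516000, next to Sε, had 1.53 motifs per 100 bases. With 983 bases read it fell short of the minimum and was counted in the stretch. Sμ spanned 114661000 to 114663999, next to the bait at 114664780 to 114664909. Sγ3 spanned 114599000 to 114603999, Sγ1 114573000 to 114576999 and Sγ2b 114547000 to 114552999. Sγ2a spanned 114528000 to 114533999, Sε 114513000 to 114515999 and Sα 114497000 to 114503999. The stretch between Sγ2a and Sε (114516000 to 114527999) holds the place of Cγ2a and of the inserted CBEs. The α unit ended at 114492000, and the region downstream of it reached from there to 114414909.

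In the starting line, most class-switch joins went to α. In NCdel the α unit (114492000 to 114508499) took 43.2% ± 7.24 (SD, n = 6) of all junctions, and the μ unit around the bait took 16.4% ± 4.03. α made up 98.2% ± 0.611 of the junctions in acceptor regions. γ3 took 0.451% ± 0.336, γ1 0.161% ± 0.0739 and γ2b 0.163% ± 0.0691 of all junctions. γ2a held 3 junctions, ε held 4, and the stretch between Sγ2a and Sε held 0 of 11564, which allows a share of up to 0.0259%.

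**Figure D1:**
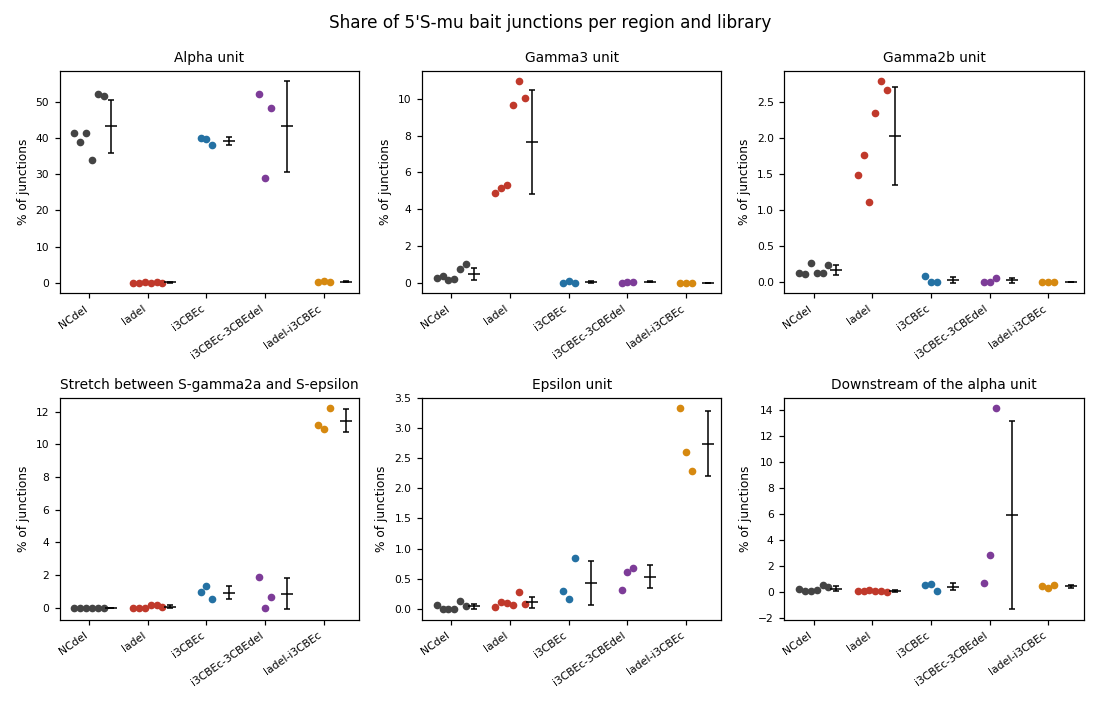
Percent of a library's junctions in each region (y axes, in percent, each panel with its own scale) for the 5 genotypes (x axis), with 1 point per library and the group mean ± SD. The α share lies between 34.0% and 52.3% in NCdel and averages 0.106% in Iadel, where γ3 and γ2b are higher.

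Deleting Iα, compared with the starting line, asks what becomes of Sμ ends when Sα is not transcribed from its own promoter. Joins to α fell and joins to γ3, γ2b and γ2a rose. The α share was 0.106% ± 0.129 in Iadel (n = 6) and 409.6-fold lower than in NCdel (782-fold without Iadel library 3, which holds 11 of the 17 α junctions). The share of γ3 was 7.67% ± 2.83 and 17.0-fold higher, and that of γ2b was 2.02% ± 0.677 and 12.4-fold higher. γ2a rose to 0.982% ± 0.353, from 3 junctions in all of NCdel. Each of these 4 differences had p = 0.00216 in an exact permutation test, the smallest that 6 against 6 libraries allow, with an adjusted p of 0.00541 and no overlap between the groups. The γ joins did not add up to the lost α joins, since all acceptor regions together fell from 44.1% ± 7.65 to 11.3% ± 4.06, 3.89-fold lower (exact permutation p = 0.00216). Among the acceptor junctions of Iadel, γ3 made up 67.5% ± 2.12, γ2b 18.1% ± 2.79, γ2a 8.89% ± 1.76, γ1 2.90% ± 1.40 and α 1.17% ± 1.72. The μ share was 19.2% ± 8.86 in Iadel and 16.4% ± 4.03 in NCdel (adjusted exact permutation p = 0.476). For γ1 the share of all junctions was 0.369% ± 0.273 (adjusted exact permutation p = 0.146), and for ε it was 0.111% ± 0.0897 (0.118); neither passed the threshold. The region upstream of the bait rose from 1.5% ± 0.288 to 1.95% ± 0.299 (adjusted exact permutation p = 0.0476). That call was lost without any 1 of NCdel libraries 2, 4, 5 and 6 or Iadel libraries 1, 4, 5 and 6, with adjusted p up to 0.0996. A fall downstream of α was called only without NCdel library 2 (-0.204 percentage points, adjusted exact permutation p = 0.0216). The share outside IgH was 67.4% ± 13.1 in Iadel and 37.8% ± 11.2 in NCdel, 1.79-fold higher (exact permutation p = 0.00216).

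Within the regions, limma called 26 of 60 bins between Iadel and NCdel, 17 higher and 9 lower in Iadel. The 9 lower bins all lay in the α unit, which has 10 tested bins, with log2 fold changes of -8.86 (SE 0.37) at 114501000 and -8.02 (SE 0.32) at 114500000. Further named bins of α were at 114502000 (-7.19), 114499000 (-7.08), 114498000 (-5.72), 114497000 (-4.85) and 114496000 (-3.75); Iadel is at 0 in the last 3, so these values depend on the pseudocount. All 5 bins of γ3 were higher, with 4.40 (SE 0.54) at 114602000, 4.27 at 114601000 and 4.12 at 114603000. Of γ2b, 5 of 6 bins were higher, with 3.58 at 114548000 and 3.28 at 114551000, and all 6 bins of γ2a were higher. The bins at 114603000, 114548000 and 114551000 passed the filter only through Iadel, with 172 of 180, 53 of 54 and 121 of 130 junctions. Their direction was thus largely fixed in advance. γ2a held 130 junctions in Iadel and 3 in NCdel, so its bins also passed largely through groups other than NCdel. Between the 3 libraries of each group in run 490, the difference was -40.4 percentage points for α, 9.97 for γ3, 2.43 for γ2b, 1.22 for γ2a, 13.5 for μ, -26.1 for all acceptors and 12.3 for the share outside IgH. In that run limma called 31 bins, of which 24 were also called over all libraries in the same direction.

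**Figure D2:**
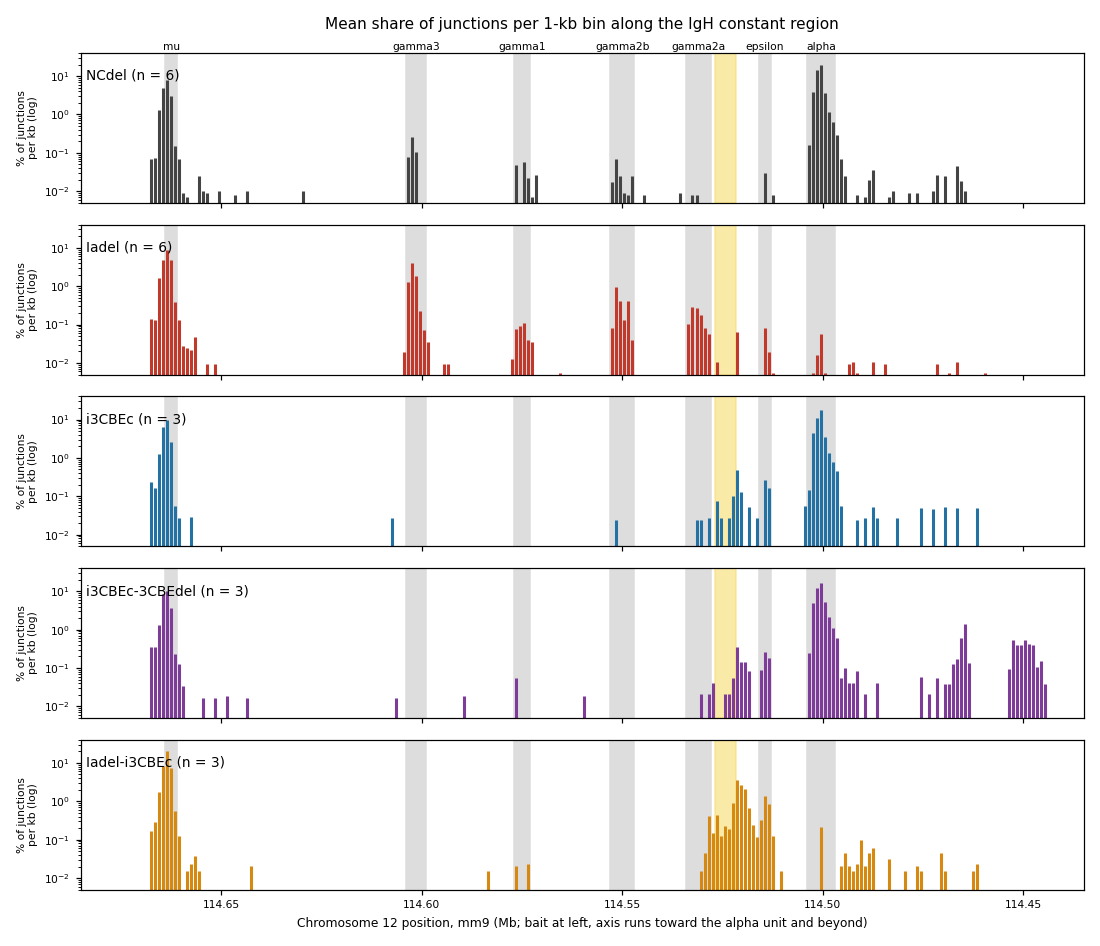
Mean percent of junctions per 1-kb bin (y axis, log scale, percent) along chromosome 12 of mm9 (x axis, position) for each of the 5 genotypes, with the switch blocks in grey and the interval that contains the insertion in yellow. Iadel shows peaks over Sγ3, Sγ2b and Sγ2a, and Iadel-i3CBEc shows its main acceptor peak in the stretch between Sγ2a and Sε, where it reaches 3.69% in the bin at 114521000.

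Adding 3 CBEs to the starting line asks whether a new CTCF-bound site changes the choice of acceptor while Iα is present. Joins to α stayed the main class, with 39.2% ± 1.10 in i3CBEc (n = 3) and 43.2% ± 7.24 in NCdel (adjusted exact permutation p = 0.370). The stretch that holds the insertion took 0.932% ± 0.422 of junctions, at least 35.9-fold higher than in NCdel, where it held 0 junctions. ε took 0.431% ± 0.366, 11.2-fold higher than in NCdel. γ2b fell to 1 junction of 3828, from 19 junctions and 0.163% ± 0.0691 in NCdel. These 3 differences had an adjusted p of 0.0397 (exact permutation p = 0.0119) and no overlap between the groups. Further upstream, i3CBEc had 0 junctions in γ1, against 18 in NCdel (adjusted exact permutation p = 0.0595), and 1 in γ3, against 52 (0.143). The acceptor total was 40.7% ± 1.19 in i3CBEc and 44.1% ± 7.65 in NCdel (exact permutation p = 0.464). limma called 6 of 60 bins, 5 higher and 1 lower, with log2 fold changes of 4.24 (SE 0.86) at 114521000, 2.66 at 114520000 and 2.42 at 114522000 in the stretch and 2.82 at 114513000 in Sε. NCdel is at 0 in these 4 bins, so the values depend on the pseudocount. The calls on the stretch, ε and γ2b were lost without any 1 library except NCdel library 2 (adjusted exact permutation p of 0.0595 to 0.179), since fewer splits remain, and the ε difference went from 0.393 to 0.185 percentage points (5.82-fold) without i3CBEc library 3 and to 19.8-fold without NCdel library 5. Per 100 junctions of the μ unit, the calls on the stretch, ε and γ2b were all lost (adjusted exact permutation p of 0.0595 to 0.0714). That on γ2b was also lost with deletional joins only (0.164) and without 10 kb around the bait (0.0595). No sequencing run holds both groups, so run and genotype cannot be told apart here.

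Adding the 3 CBEs to Iα-deleted cells asks the same question where α is no longer the main acceptor. The shares of γ3 and γ2b, upstream of the insertion, fell, and that of the stretch around it rose. In Iadel-i3CBEc (n = 3) the stretch took 11.4% ± 0.697 of junctions, 156-fold more than in Iadel, which held 7. Those 7 were all in libraries of run 490, 6 of them at the single position 114521585, and Iadel libraries 1 to 3 held 0, so the size of this fold rests on few reads. ε rose 24.7-fold to 2.74% ± 0.540, and the region downstream of α rose 5.66-fold to 0.431% ± 0.118. γ3 had 0 of 5152 junctions, at least 132-fold lower than in Iadel, and γ2b had 0, at least 34.7-fold lower. These 5 differences had an adjusted p of 0.0238 (exact permutation p = 0.0119) without overlap. The μ unit rose 1.91-fold to 36.6% ± 1.67 (adjusted exact permutation p = 0.0397). γ2a, just upstream of the insertion, was at 0.480% ± 0.0565 against 0.982% ± 0.353 in Iadel (adjusted exact permutation p = 0.0510). Of its 25 junctions in Iadel-i3CBEc, 22 lay in the bin at 114528000, next to the stretch. The bins at 114531000, 114532000 and 114533000 held 0. Of the 6 bins of γ2a, limma called 1 higher and 3 lower than in Iadel. α was at 0.317% ± 0.166 against 0.106% ± 0.129 (0.0893), and γ1 at 0.0598% ± 0.0115 against 0.369% ± 0.273 (0.106). The acceptor total was 15.0% ± 0.387 against 11.3% ± 4.06 (exact permutation p = 0.238). The stretch made up 76.1% ± 3.89 and ε 18.2% ± 3.41 of the acceptor junctions of Iadel-i3CBEc. With the stretch and γ2a taken as 1 unit, as in the design, its share was 11.9% ± 0.643 against 1.06% ± 0.433 (exact permutation p = 0.0119). The share outside IgH fell from 67.4% ± 13.1 to 45.7% ± 1.81 (exact permutation p = 0.0238).

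Of the 587 junctions in the stretch of Iadel-i3CBEc, 383 (65.2%) lay on the α side of the interval that contains the insertion, 186 lay within it and 18 on the μ side. Their median position was 114520997, with quartiles at 114519888 and 114521751. limma called 30 of 60 bins, 16 higher and 14 lower, and all 9 bins of the stretch and all 3 of ε were higher. The stretch bin at 114517000 held junctions of Iadel-i3CBEc alone and passed the filter only through that group. Those at 114518000, 114519000, 114522000, 114523000, 114524000 and 114526000 also passed only through it. Iadel-i3CBEc held 35 of 41, 103 of 110, 45 of 52, 9 of 11, 11 of 12 and 23 of 27 junctions there, in that order. In ε the bin at 114515000 did so too (18 of 24). That these bins were higher was thus largely fixed in advance. In the stretch the log2 fold changes were 6.91 (SE 0.55) at 114520000, 6.53 at 114519000, 6.27 at 114521000, 5.34 at 114522000, 4.99 at 114518000 and 4.15 at 114526000. In Sε they were 4.66 at 114513000 and 4.03 at 114514000. All 5 bins of γ3 and 5 of 6 of γ2b were lower, with -7.01 at 114602000, -5.95 at 114601000, -5.39 at 114603000 and -4.89 at 114551000; these values depend on the pseudocount, since Iadel-i3CBEc is at 0 there, as do those of the stretch at 114518000 to 114520000 and 114522000, where Iadel is at 0. The bins at 114603000 and 114551000 passed the filter only through Iadel, with 172 of 180 and 121 of 130 junctions. The calls on the stretch, ε, γ2b and the downstream region were lost without Iadel library 2 or any 1 library of Iadel-i3CBEc (adjusted exact permutation p of 0.0595 to 0.0714), and that on γ3 also without Iadel library 3 (0.0510). That on μ was lost without any 1 library (adjusted exact permutation p of 0.0510 to 0.119), and that on the share outside IgH without any 1 of Iadel libraries 1 to 3 or of Iadel-i3CBEc (exact permutation p of 0.0714 to 0.143). Differences were called without Iadel library 3 for α (0.261 percentage points) and without Iadel library 5 for the acceptor total (4.65), each with an exact permutation p, adjusted for α, of 0.0357. Between the 3 libraries of each group in run 490, the difference was 11.3 percentage points for the stretch, -10.2 for γ3, -2.59 for γ2b, 2.60 for ε, 9.34 for μ, 0.0344 for all acceptors and -9.84 for the share outside IgH.

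The insertion effect was compared between Iα-deleted and Iα-bearing cells. The stretch differed by 11.4 percentage points with the insertion in deleted cells and by 0.932 in the others, and ε by 2.63 and 0.393. γ3 differed by -7.67 and -0.425, γ2b by -2.02 and -0.139, and γ2a by -0.502 and 0.0498. The relabelings set in advance compare with no insertion effect in either background, so they were repeated, after the data were seen, with a common effect taken out first. The effects then differed by 10.4 for the stretch, 2.24 for ε and -1.88 for γ2b (each with an adjusted exact permutation p of 0.0227), and by -7.25 for γ3 (0.0400). With only libraries 4 to 6 of the 6-library groups, the stretch was not called (adjusted exact permutation p = 0.167, with the relabelings set in advance). For γ2a the difference was -0.552 (adjusted exact permutation p = 0.0836, and 0.0422 with the relabelings set in advance). For μ it was 14.8 (adjusted exact permutation p = 0.0836), for α 4.23 (0.427) and for the acceptor total 7.07 (exact permutation p = 0.209). limma called 26 of 60 bins for this difference, 12 higher and 14 lower.

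Iadel-i3CBEc against i3CBEc asks what the Iα deletion changes once the insertion is present. The α share was 124-fold lower, at 0.317% ± 0.166 against 39.2% ± 1.10 (n = 3 each). The stretch was 12.3-fold higher, ε 6.35-fold higher (12.3-fold without i3CBEc library 3) and the μ unit 1.92-fold higher in Iadel-i3CBEc. The acceptor total was 2.71-fold lower, at 15.0% ± 0.387 against 40.7% ± 1.19. γ3 held 0 and 1 junctions, γ2b 0 and 1, γ1 3 and 0, and γ2a 25 and 3, in Iadel-i3CBEc and i3CBEc. For α, the stretch, ε, μ, γ2a and the acceptor total the groups did not overlap, but 3 against 3 libraries cannot give an exact permutation p below 0.1, the value found. limma, which shares its estimate of spread over all groups, called 24 of 60 bins, 16 higher and 8 lower. The log2 fold changes in α were -8.58 (SE 0.52) at 114501000, -7.23 at 114502000, -6.91 at 114499000, -6.20 at 114500000, -5.58 at 114498000, -4.63 at 114497000 and -3.94 at 114496000. In these bins, except that at 114500000, Iadel-i3CBEc is at 0 and the values depend on the pseudocount. In the stretch they were 5.70 at 114519000 (where i3CBEc is at 0), 4.0 at 114520000 and 3.39 at 114518000, with 2.98 at 114528000 in Sγ2a and 2.96 at 114661000 in Sμ. The stretch bins at 114518000 and 114519000 passed the filter only through Iadel-i3CBEc, with 35 of 41 and 103 of 110 junctions. The groups share no sequencing run.

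Deleting the 3′CBEs from cells with the insertion asks whether the outcome of the insertion depends on them. The α share was 43.2% ± 12.5 in i3CBEc-3CBEdel (n = 3), 39.2% ± 1.10 in i3CBEc (exact permutation p = 0.7) and 43.2% ± 7.24 in NCdel (exact permutation p = 1). The stretch was at 0.854% ± 0.955, against 0.932% ± 0.422 in i3CBEc, but its 3 libraries held 30, 0 and 12 junctions there. Without library 1 the stretch was 2.75-fold lower than in i3CBEc, and without library 2 it was 1.37-fold higher. ε was at 0.533% ± 0.192, against 0.431% ± 0.366. γ3 held 2 junctions, γ1 3, γ2b 1 and γ2a 2. The region downstream of α took 5.89% ± 7.24 of junctions, 14.4-fold more than in i3CBEc without overlap (4.32-fold without i3CBEc-3CBEdel library 3), and the 3 libraries differed widely. They held 11 junctions (0.691%, 95% Wilson interval 0.386 to 1.23), 56 (2.83%, 2.19 to 3.66) and 251 (14.2%, 12.6 to 15.9). Against i3CBEc no region was called, since 3 against 3 libraries cannot give an exact permutation p below 0.1, which was found for the downstream region and for μ (22.8% ± 1.10 against 19.0% ± 1.21). limma called 8 of 60 bins, all higher and all among the 10 bins downstream of α, with log2 fold changes of 3.66 (SE 0.83) at 114464000, a bin that also met the AGCT minimum of a switch block, and 2.57 (SE 0.81) at 114465000. i3CBEc is at 0 in both, so these values depend on the pseudocount. The bins at 114447000 to 114452000 held junctions of i3CBEc-3CBEdel alone. They passed the filter only through that group, so their direction was fixed in advance. Those at 114464000 and 114465000 also passed only through that group, which held 76 of 77 and 33 of 35 junctions. Their direction was thus largely fixed as well. limma called 0 bins without i3CBEc library 1, 1 higher and 1 lower without library 2, and 1 higher without library 3. Without i3CBEc-3CBEdel library 2 it called 3 higher bins, and without library 3 it called 0 higher and 1 lower. With a pseudocount of 2 it called 0.

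Against the starting line, i3CBEc-3CBEdel was 24.3-fold higher in the region downstream of α and 13.9-fold higher in ε, and γ2b fell to 1 junction of 5342. These 3 differences had an adjusted p of 0.0397 (exact permutation p = 0.0119). The stretch, at 0 in NCdel, had an adjusted exact permutation p of 0.119. limma called 20 of 60 bins, 17 higher and 3 lower, with log2 fold changes of 3.98 (SE 0.72) at 114464000 downstream of α, 3.03 at 114513000 and 2.10 at 114515000 in Sε, 2.33 at 114666000 upstream of the bait and -1.68 at 114551000 in Sγ2b. NCdel is at 0 in both Sε bins and i3CBEc-3CBEdel in that of Sγ2b, so these 3 values depend on the pseudocount. The bin at 114464000 passed the filter only through i3CBEc-3CBEdel, which held 76 of its 77 junctions, so its direction was largely fixed in advance. The same holds for the bins at 114447000 to 114452000 and 114465000. Each of the 3 region calls was lost without any 1 library (adjusted exact permutation p of 0.0595 to 0.204), and the downstream difference of 5.65 percentage points was 1.52 (7.27-fold) without i3CBEc-3CBEdel library 3, where limma called 13 bins. ε was 24.4-fold higher without NCdel library 5. A lower share outside IgH was called only without i3CBEc-3CBEdel library 2 (-22.4 percentage points, exact permutation p = 0.0357). Neither comparison has a shared sequencing run, so run and genotype cannot be told apart.

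Joins by deletion to an acceptor region restore a switched gene, and joins by inversion do not. In μ and upstream of the bait no switch is made, and deletional names the prey strand alone. In NCdel 97.4% ± 0.837 (n = 6) of α junctions were deletional. This share was 81.1% ± 1.16 in i3CBEc and 80.3% ± 0.990 in i3CBEc-3CBEdel, both lower than in NCdel (adjusted exact permutation p = 0.0179 each), with no sequencing run shared with NCdel. In the μ unit it fell from 89.4% ± 2.73 in NCdel to 81.0% ± 1.17 in i3CBEc and 77.5% ± 5.87 in i3CBEc-3CBEdel (0.0179 each, adjusted exact permutation p). It was 90.5% ± 2.02 in Iadel and 89.3% ± 1.14 in Iadel-i3CBEc. In γ3 of Iadel it was 94.5% ± 2.11, and in the stretch of Iadel-i3CBEc 82.6% ± 5.41. In the stretch of i3CBEc 20 of 36 junctions were deletional, with 58.4% ± 17.3 in the 2 libraries of at least 10 junctions there. In that of i3CBEc-3CBEdel 31 of 42 were (69.2% ± 15.3, n = 2). Upstream of the bait, the share of preys on the bait's strand fell from 87.1% ± 2.39 in Iadel to 73.0% ± 4.61 in Iadel-i3CBEc. It also fell from 82.1% ± 5.44 in NCdel to 54.8% ± 18.6 in i3CBEc-3CBEdel (adjusted exact permutation p = 0.0238 each). In α, 57.0% ± 2.01 of NCdel junctions had microhomology, 21.6% ± 2.00 were direct and 21.4% ± 1.31 had inserted bases. With i3CBEc these were 57.6% ± 1.38, 20.6% ± 3.54 and 21.8% ± 2.18, and none differed past the threshold. Against NCdel, i3CBEc-3CBEdel had more joins with inserted bases upstream of the bait, 17.0% ± 2.69 against 6.41% ± 4.94, and in α, 23.7% ± 0.743 against 21.4% ± 1.31 (adjusted exact permutation p = 0.0476 each).

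**Figure D3:**
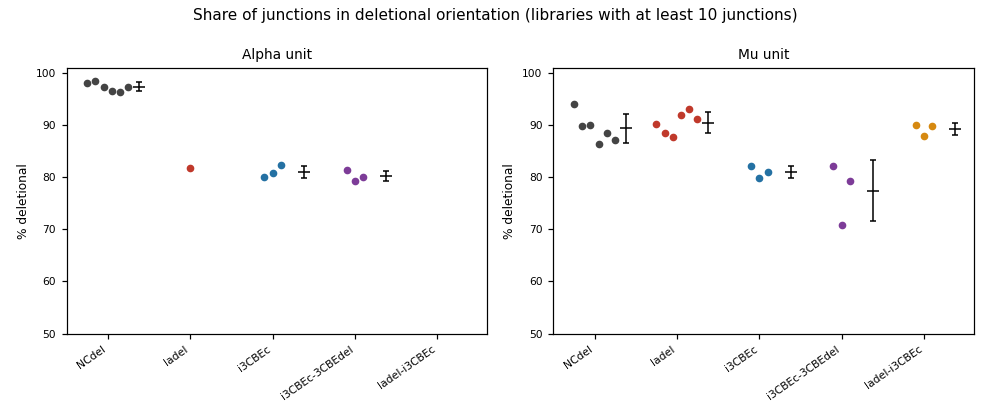
Percent of junctions joined by deletion (y axis, percent) in the μ and α units by genotype (x axis), with 1 point per library of at least 10 junctions in the unit and the group mean ± SD. In α the NCdel libraries lie between 96.4% and 98.5%, above every library of i3CBEc and i3CBEc-3CBEdel.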

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

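All weighing tests in this part were chosen after the results were seen, and the counts of splits of the samples were run on the planned bin counts; taking out a common effect was also chosen then.

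The effect of the 3 inserted CBEs differed between cells with and without the Iα deletion in 4 regions, once a common effect of the insertion was taken out before the relabelings. The difference was 10.4 percentage points for the stretch between Sγ2a and Sε, 2.24 for ε, -7.25 for γ3 and -1.88 for γ2b, each as the effect with the deletion minus the effect without it (adjusted exact permutation p of 0.0227 to 0.0400). That of the stretch was not called with only libraries 4 to 6 of the 6-library groups, under the relabelings set in advance (adjusted exact permutation p = 0.167). NCdel itself held 52 junctions in γ3 and 19 in γ2b, which leaves little room for a fall in these regions without the deletion. The matching limma count was 26 bins, with the effect in Iα-deleted cells taken out as the common one. It was reached by 2 of 100 splits, the real one included, and the other gave 27 bins. Chance is thus argued against but not excluded. In cells with Iα no run holds both groups, so the splits cannot exclude a run effect there. With the mean of both effects taken out, the real count was 25, with 14 as the highest of the others.

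In 21 tests of groups with 6 libraries, 2 libraries stood far from the others of their group, where chance gives about 1 in 20. The ε share of Iadel library 5 was 0.284%, with the next highest library at 0.114%. The α share of Iadel library 3 was 0.357%, with the next highest also at 0.114%.

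For the other bin counts with enough splits, the real split gave more bins than any other tried. This argues against a chance division of the libraries. It does not exclude a run effect for i3CBEc or i3CBEc-3CBEdel against NCdel, where no run holds both groups. The 26 bins of Iadel against NCdel were reached by 1 of 100 splits, the real one, with 23 as the highest of the others. The 6 bins of i3CBEc against NCdel were reached by 1 of 84 (highest other 2), the 30 of Iadel-i3CBEc against Iadel by 1 of 84 (highest other 17), and the 20 of i3CBEc-3CBEdel against NCdel by 1 of 84 (highest other 9). Between 3 and 3 libraries there are 10 splits, too few for a share under 0.05. There the real count was 8 with 8 as the highest other, reached by 2 splits, for i3CBEc-3CBEdel against i3CBEc, and 24 with 0 as the highest other, reached by 1 split, for Iadel-i3CBEc against i3CBEc.

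The share of junctions outside IgH was higher in Iadel than in NCdel, and it also differed between sequencing runs. Run cannot be the whole cause, since within run 490 the Iadel libraries lay 12.3 percentage points above those of NCdel (55.5% ± 1.07 against 43.3% ± 0.104, n = 3 each). Run may be part of it, as the Iadel libraries of run 482 lay 23.8 percentage points above those of run 490. A loss of acceptor joins, which leaves a larger part to all other joins, may be another part: among junctions outside acceptor regions in run 490, the share outside IgH was -8.17 percentage points different in Iadel, that is lower. A change in the rate of joining outside IgH was not tested, since shares give no absolute rate.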

How the results depend on the processing

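No called region share changed its sign under the alternatives. Bin counts were compared by size and not by sign. That of i3CBEc-3CBEdel against i3CBEc went from 8 higher bins to 0 higher and 1 lower without i3CBEc-3CBEdel library 3. There were 57 sign changes over 22 results, all of results that were not called over all libraries, 3 of which were called under the alternative. With 1 library left out, fewer splits remain and the smallest p rises. Of the checks of called regions that left out a library of a group of 3, 9 of 9 lost the call for i3CBEc against NCdel, 18 of 18 for Iadel-i3CBEc against Iadel and 9 of 9 for i3CBEc-3CBEdel against NCdel. When the library was from a group of 6, 15 of 18, 12 of 36 and 18 of 18 did, in the same order. Of 60 such checks for Iadel against NCdel 8 lost the call, all on the upstream region (adjusted p of 0.0476 over all libraries), and γ3, γ2b, γ2a and α kept it in each. Over the shares not set as a comparison's first answer, which include γ3, γ2b, γ2a and ε, 679 of 871 checks, left-out libraries included, kept direction and call, 146 lost the call, 18 gained it and 28 changed sign. All 17 called regions, among them γ3, γ2b, γ2a and ε, lost the call with the replicate block, with libraries 1 to 3 only and with libraries 4 to 6 only (adjusted exact permutation p of 0.0781 to 1), and all 11 that could be tested did so in run 490 alone (0.111). They kept their direction, but the upstream difference of Iadel against NCdel shrank to 0.0170 with libraries 1 to 3. Per 100 junctions of the μ unit 8 of 16 lost the call: the upstream region in Iadel against NCdel, the downstream region in Iadel-i3CBEc against Iadel, γ2b, ε and the stretch in i3CBEc against NCdel, and γ2b, ε and the downstream region in i3CBEc-3CBEdel against NCdel. With deletional joins only 4 of 17 did: γ2b in i3CBEc against NCdel and those last 3. Without 10 kb around the bait 6 of 17 did: the same 4, the upstream region in Iadel against NCdel and μ in Iadel-i3CBEc against Iadel. Voom weights kept each of the 7 bin counts within 1.5 times, and counting repeats once ended only the upstream call of Iadel against NCdel. Depth limits the γ regions, ε and the stretch, where many groups hold under 10 junctions.

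Leaving out 1 library, the difference in the stretch ranged from 0.722 to 1.14 percentage points for i3CBEc against NCdel (8 of 9 lost the call) and from 10.97 to 11.6 for Iadel-i3CBEc against Iadel (4 of 9). For the latter comparison the range was 0.116 to 0.266 for α, 2.89 to 4.65 for the acceptors and -24.4 to -19.3 for the share outside IgH. The share outside IgH ranged from -22.4 to -6.78 for i3CBEc-3CBEdel against NCdel. Bin counts ranged from 0 to 8 for i3CBEc-3CBEdel against i3CBEc and from 13 to 24 for i3CBEc-3CBEdel against NCdel. Some results that were not called ranged across 0. For i3CBEc-3CBEdel against i3CBEc these were the upstream region (-0.0221 to 0.685), γ3 (-0.00412 to 0.0357), γ2b (-0.0240 to 0.0188), γ2a (-0.0744 to 0.00213), the stretch (-0.593 to 0.349), ε (-0.0349 to 0.309), α (-0.557 to 11.1) and the acceptors (-0.901 to 11.6). Against NCdel they were γ2a (-0.0246 to 0.0382), α (-4.57 to 7.09) and the acceptors (-4.27 to 8.20). The others were the upstream region (-0.0368 to 0.347) and the share outside IgH (-2.44 to 2.84) for i3CBEc against NCdel, and the downstream region (-0.139 to 0.137) for Iadel-i3CBEc against i3CBEc.

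With 5-kb bins, which are fewer, limma called 9 bins for Iadel against NCdel, 14 for Iadel-i3CBEc against Iadel, 4 for i3CBEc-3CBEdel against i3CBEc, 10 for i3CBEc-3CBEdel against NCdel, 7 for Iadel-i3CBEc against i3CBEc and 7 for the difference of insertion effects. With a filter of 50 junctions, which also leaves fewer bins, the counts were 13 for Iadel against NCdel, 16 for Iadel-i3CBEc against Iadel, 1 for i3CBEc-3CBEdel against i3CBEc, 11 for i3CBEc-3CBEdel against NCdel and 13 for the difference of effects. Without a filter i3CBEc against NCdel had 10, and with a pseudocount of 2 i3CBEc-3CBEdel against i3CBEc had 0 (the cause was not tested).

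With the replicate number as a block, i3CBEc-3CBEdel against i3CBEc had 1 bin, and calls were lost with fewer splits for α in Iadel against NCdel (-43.1, adjusted exact permutation p = 0.0781) and for the stretch in Iadel-i3CBEc against Iadel (11.4) and in i3CBEc against NCdel (0.932). The share outside IgH in Iadel-i3CBEc against Iadel was no longer called either and went from -21.8 to -33.7, since the block leaves only Iadel libraries 1 to 3, all of run 482. With the block the sign changed, uncalled, for i3CBEc against NCdel in the upstream region (-0.0782) and in the share outside IgH (-5.01), and for α in i3CBEc-3CBEdel against NCdel (2.70). The numbers do not pair the libraries: over 33 pairs with the same number, the correlation of residuals had a median of -0.153, so the test without a block stands first. Only libraries 1 to 3 of the 6-library groups gave -40.3 for α, -33.4 for the acceptors and 36.1 for the share outside IgH in Iadel against NCdel, -33.7 for that share and 11.4 for the stretch in Iadel-i3CBEc against Iadel, and 0.932 for the stretch in i3CBEc against NCdel. With them the sign changed, uncalled, for μ (-2.65) and γ1 (-0.00463) in Iadel against NCdel, and for the upstream region (-0.0782), the share outside IgH (-5.01) and α (2.70) as with the block. Only libraries 4 to 6 gave -45.9, -32.0 and 23.2, then -9.84 and 11.3, then 0.932, in the same order. The stretch in the difference of insertion effects was then 10.4 and no longer called (adjusted exact permutation p = 0.167, with the relabelings set in advance). With these libraries the sign changed, uncalled, for μ in i3CBEc against NCdel (-0.0603) and for the acceptors in i3CBEc-3CBEdel against NCdel (-2.28). Run 490 alone, chosen after seeing the data, gave -40.4, -26.1 and 12.3, then -9.84 and 11.3. In these settings comparisons of 3 against 3 libraries cannot pass 0.05, a limit that does not apply to the difference of insertion effects.

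Among acceptor junctions alone α was called as different by -1.83 percentage points in i3CBEc (adjusted exact permutation p = 0.0298) and -1.45 in i3CBEc-3CBEdel (0.0476) against NCdel, and by 2.79 in the difference of insertion effects (0.0403, with the relabelings set in advance, which do not take out a common effect). Per 100 junctions of the μ unit, which moves with the share of μ, the acceptor total reversed to -79.0 for i3CBEc-3CBEdel against NCdel (exact permutation p = 0.0476) and to -21.1 for Iadel-i3CBEc against Iadel (0.0357), and the upstream region to -5.60 for the latter (adjusted 0.0340), all 3 called on this scale. On that scale the stretch in i3CBEc against NCdel was 4.82 (adjusted exact permutation p = 0.0595) and the share outside IgH in Iadel against NCdel 207, neither called. Uncalled sign changes on it were, for the upstream region, -1.25 in i3CBEc against NCdel, -0.808 in i3CBEc-3CBEdel against NCdel and -2.44 in Iadel-i3CBEc against i3CBEc. For i3CBEc-3CBEdel against i3CBEc they were -18.1 for α and -19.3 for the acceptors. For the share outside IgH they were -50.5 in i3CBEc against NCdel and -77.1 in Iadel-i3CBEc against i3CBEc, where the downstream region was at -0.913; the cause was not tested. Without junctions within 10 kb of the bait the acceptor total of Iadel-i3CBEc against Iadel was called at 9.57 percentage points (exact permutation p = 0.0238). There μ, which then lacks the part next to the bait, was at -0.0275 in Iadel and -0.0597 in i3CBEc against NCdel, and α at 4.43 in i3CBEc-3CBEdel against NCdel, all uncalled. With deletional joins only, uncalled sign changes were -0.310 for the upstream region in Iadel-i3CBEc against Iadel, -0.177 for that region and 0.101 for the stretch in i3CBEc-3CBEdel against i3CBEc, -4.71 for the acceptors in i3CBEc-3CBEdel against NCdel and -0.0953 for the downstream region in Iadel-i3CBEc against i3CBEc.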

Other observations

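The tests of explanations in this part were all chosen after the results were seen; the naming of the 10 bins outside IgH was planned.

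Outside IgH, 20119 junctions fell into 12645 bins of 100 kb on 21 chromosomes, and 8023 of these bins held 1 junction. There were 1209 bins with junctions of at least 3 libraries, and the 10 with the most junctions held 3.03% of the total. The first lay on chromosome 14 from 32400001 to 32500000, with 293 junctions in all 21 libraries and 0.185% to 1.52% of a library. Of these, 86 were at position 32427222, where 89.5% had inserted bases against 22.2% elsewhere in the bin, and 274 had the prey on the plus strand. Per 10000 junctions this bin had 45.0 in NCdel, 77.2 in Iadel, 41.8 in i3CBEc, 76.8 in i3CBEc-3CBEdel and 138 in Iadel-i3CBEc. The next were chromosome 2 from 98500001 (71 junctions) and chromosome 12 from 81200001 (54), 63300001 (51 at 19 positions) and 116300001 (37). The others were chromosome 19 from 35300001 (27), chromosome 8 from 125900001 (20), chromosome 12 from 56500001 (19), chromosome X from 131700001 (19 at 2 positions) and chromosome 12 from 113800001 (18). Whether the bins on chromosome 12, such as that from 116300001, lie within the IgH locus was not checked, as no mm9 annotation was at hand. The prey was on the plus strand in 50.5% of junctions outside IgH.

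Iadel, which carries no insertion, held 7 junctions in the stretch between Sγ2a and Sε. All 7 were in libraries of run 490, which also holds the Iadel-i3CBEc libraries, and 6 of them, from 3 libraries, were at the single position 114521585. The cause was not tested.

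α joins were less often deletional in both insertion lines that keep Iα than in NCdel. Random variation between sequencing runs is argued against by an exact permutation of run means, with p = 0.0286 for 4 against 3 runs (79.4% to 81.4% against 96.6% to 98.03%). Short preys placed on the wrong strand are argued against as well, since the difference was -17.6 percentage points for preys of at least 100 bases (80.1% ± 2.18 against 97.6% ± 1.35). An effect of the insertion in any background stays open: between Iadel-i3CBEc and Iadel the deletional share differed by -1.18 percentage points in μ but by -14.1 upstream of the bait, and α held only 16 junctions in Iadel-i3CBEc, 14 of them deletional (87.5%, 95% Wilson interval 64.0 to 96.5). Also open are a change in handling tied to the runs of these groups, as no run holds NCdel with either line, and a change in these lines themselves, which may differ from NCdel in more than the insertion.

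Downstream of α, i3CBEc-3CBEdel held 318 junctions, with 150 between α and 114463298, 168 beyond the 9302 bases from 114453997 to 114463298, and 0 within these; the 168 came from libraries 2 (47) and 3 (121), and library 1 had none of its 11 there. Repeat reads of few molecules are argued against by the number of distinct junctions, 317 of 318 by prey position, strand and bait end. Their share, 99.7%, is no test in itself, since the deposited lines had already passed a duplicate filter. Sequence that cannot be mapped is argued against as the source of the empty interval in part of it, because other groups had 5 of their 78 downstream junctions there. These lay in the bins at 114459000, 114461000 and 114462000. Between the bins at 114453000 and 114459000 no library of any group had a junction, so for that part this explanation stays open. A candidate explanation is that the interval is, or lies in, the segment deleted with the 3′CBEs. Fisher's exact test of the other groups against i3CBEc-3CBEdel gave p = 0.000267, but the bounds were taken from the same junctions, so that this stays open, as does the reason why the 3 libraries, each from its own run, differ.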
